A study of Sus scrofa with 5 samples.

How the data were processed

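RNA sequencing was analysed from ovarian follicles of female Indian Ghoongroo pigs, a domestic breed of Sus scrofa, in 5 libraries: 3 of large follicles and 2 of small follicles. Groups and replicate numbers were taken from the sample titles. Per the labels, the replicates are biological. Whether they came from separate animals, how many follicles entered each library, and the follicle diameters are not given in the sources used here, so p-values measure only the spread between these samples. Per the labels' protocols, total RNA was isolated with TRIzol and paired-end libraries were made with a stranded mRNA kit.

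The deposited files hold FPKM values per gene, that is, fragments scaled by gene length and library total, which the authors computed. The submitters' processing notes name FastQC 0.11.4, Trimmomatic 0.38, HISAT2 2.0.5, StringTie 1.3.3, featureCounts 1.5.0-p3 and the genome build Sscrofa11.1, with no role or order. Whether counting used the strand, and how fragments shared by near-identical genes were assigned, is not given in the sources used here. Each file lists 30822 genes with identical annotation columns. Of these, 30335 gene identifiers were matched to a RefSeq gene table of the same assembly, which gave chromosome numbers and restored 26 symbols that had been turned into dates.

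Library totals were worked back from the smallest steps of the FPKM values. They were 11507527, 9991708 and 10462325 fragments in large follicle replicates 1, 2 and 3, and 9523739 and 10038500 in small follicle replicates 1 and 2. Of the 23353 genes above 0 in any library, 49.5% gave whole fragments, within 0.001 of a fragment, with the listed gene length. The other 11791 did so with a shorter length found by search, a weak check for the 2002 genes above 0 in 1 library only. Recovered fragments summed to between 99.5% and 99.6% of the totals. At these depths 3 fragments in a gene of 2000 bases correspond to 0.130 to 0.158 FPKM. Confidence intervals of shares are Wilson 95% intervals. Such intervals and floors cover counting error only.

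Genes with an FPKM of 1 or more in at least 2 libraries were tested, 13087 in all. The test was the moderated two-sided test of limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1) with the group as the only term and Benjamini-Hochberg adjustment over the genes tested. A gene is called at an adjusted p under 0.05. Fold changes are given as large minus small on the log2(FPKM + 1) scale, which understates the change of low genes; values after ± are SD for FPKM and SE for log2 fold changes. Gene lists (31) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, again with the correlation estimated, and with fry. A duplicated symbol was represented by its protein-coding row of highest mean.

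Named genes followed a fixed rule: the 10 largest changes in each direction among called genes with a symbol, a mean FPKM of at least 5 and no overlap between the groups; 16 follicle genes named whether called or not; and up to 4 members of each list with the smallest p. Placeholder symbols beginning with LOC were not counted as symbols, a reading chosen after the data were examined. The groups, the tests, the gene lists and this rule were fixed before the data were examined, as were the alternatives except those named as later additions. Alternatives covered other pseudocounts (0.1 and 5), no filter or a mean FPKM of at least 5, median-of-ratios scaling, scaling to a common sum, quantile normalization, a replicate block, other variance models, library weights, protein-coding genes only, each library left out, and limma voom on the recovered fragments.

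The fit was tested on simulated libraries drawn from the means, totals and spread of the 13087 genes in the comparison of large with small follicles, in 20 runs with 200 changed genes each. It recovered 17.9% of genes changed 2-fold, 89.3% of those changed 4-fold and 98.2% of those changed 8-fold. False calls made up 7.58% of all calls. The simulated genes varied independently, with 58 calls in all when no gene was changed. Camera found a list of 40 genes changed 1.5-fold in 20 runs and called 0 of 200 lists without change. Independent genes do not cover differences that many genes share within a library.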

Results

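Gene expression was measured in 3 libraries of large and 2 libraries of small ovarian follicles from Indian Ghoongroo pigs. The study design asks which genes differ between the 2 follicle sizes. Library totals ranged from 9523739 to 11507527 fragments, and between 11784 and 13064 genes per library reached an FPKM of 1. No pair of libraries of 1 group agreed within sampling noise: the chi-square per degree of freedom over genes was at least 35.2, so each library was counted as 1 sample.

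Large follicles had far more RNA for the androgen-forming enzyme CYP17A1 and less for the inhibin and activin subunit INHBB. CYP17A1 (gene 403330, Sscrofa11.1 chromosome 14, 113805616 to 113820445), which turns progestagens into androgens in theca cells, rose 9.65-fold, from 146 ± 1.45 FPKM (SD, n = 2) in small to 1407 ± 918 FPKM (SD, n = 3) in large follicles. Its limma adjusted p was 0.0121, and 0.140 with no filter on low values; without large follicle replicate 2 the rise was 6.07-fold. INHBB (gene 397490, chromosome 15, 30999994 to 31004405), a subunit of inhibin B and activin B made by granulosa cells, was 8.37-fold higher in small follicles, at 232 ± 157 FPKM (SD, n = 2) against 27.7 ± 11.99 FPKM (SD, n = 3), with a limma adjusted p = 0.0237. Without small follicle replicate 2 the fold of INHBB was 4.35 (limma adjusted p = 0.0817), and without large follicle replicate 1 its limma adjusted p was 0.0775. LCN2, a secreted iron-siderophore binding protein of neutrophils and epithelia, and GSTA1, a glutathione transferase, rose 40.2-fold and 22.6-fold. PLA2G1B, a secreted phospholipase, fell from 29.9 ± 1.26 FPKM in small follicles to a level near the counting floor in large ones.

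Of 13087 genes tested, 128 were called by limma at a Benjamini-Hochberg adjusted p under 0.05, 70 higher and 58 lower in large follicles. At an unadjusted p under 0.05 there were 1365. The values of all 128 called genes did not overlap between the groups. Among all genes tested 26.1% did not overlap, where chance gives 20% for 3 against 2. The count rested on single libraries: it was 29 without large follicle replicate 1, 268 without replicate 2, 222 without replicate 3, 78 without small follicle replicate 1 and 60 without small follicle replicate 2. Limma voom on the recovered fragments called 70 genes, and 65 of them were among the 128.

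Among the largest rises, LCN2 (chromosome 1, 268609975 to 268614651) had 62.0 ± 28.5 against 1.54 ± 0.635 FPKM (log2 fold change 4.56, SE 0.35, limma adjusted p = 0.000551). GSTA1 (chromosome 7, 46538743 to 46550781) had 1178 ± 365 against 52.2 ± 7.44 FPKM (log2 fold change 4.42, SE 0.30, limma adjusted p = 0.000551). A neighbouring copy annotated as similar to GSTA1 was also called, at 247 ± 30.4 against 65.2 ± 0.305 FPKM, so fragments shared between the copies leave the GSTA1 level uncertain. PENK, the precursor of enkephalin peptides, rose 11.6-fold to 38.5 ± 5.60 FPKM (log2 fold change 3.18, SE 0.23, limma adjusted p = 0.000551). SULT2A1, a steroid sulfotransferase, and HDC, which forms histamine, had log2 fold changes of 2.99 ± 0.39 and 2.59 ± 0.30. LYZ, the lysozyme of myeloid cells, rose 7.40-fold (log2 fold change 2.74, SE 0.21, limma adjusted p = 0.000551). FBXO2, a ubiquitin ligase subunit that binds glycoproteins, and CHI3L1, a secreted chitinase-like protein, had log2 fold changes of 2.91 ± 0.38 and 2.79 ± 0.43. MIR9788-1, a microRNA locus, had 49.1 ± 12.03 against 2.63 ± 3.71 FPKM, from at most 36 fragments in a library of an mRNA kit, which need not come from the mature microRNA. The naming rule left out 28 called genes with LOC placeholder symbols, some with changes as large. LOC110260659, annotated as a tumor protein pseudogene, had a log2 fold change of 3.55 ± 0.29 (limma adjusted p = 0.000782). In the other direction, LOC110256043 had -2.53 ± 0.28 (limma adjusted p = 0.00380). Some folds of FPKM means moved with 1 library. Without small follicle replicate 1 they were 23.7 against 37.5 for SULT2A1, 16.7 against 10.7 for FBXO2 and 9.51 against 19.0 for CHI3L1. Without small follicle replicate 2 they were 89.8 for SULT2A1, 9.23 against 6.05 for HDC and 9.35 against 18.7 for MIR9788-1. The SULT2A1 folds divide by only 1 and 4 fragments in small follicle replicates 1 and 2, so their size is uncertain. CHI3L1 had 0 and 17 fragments there, so it has no defined fold without small follicle replicate 2.

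Among the largest falls, PLA2G1B (chromosome 14, 40314520 to 40322315) had 0.384 ± 0.403 against 29.9 ± 1.26 FPKM (log2 fold change -4.52, SE 0.32, limma adjusted p = 0.000551), from 2, 4 and 0 fragments in the large follicle libraries. RARRES1, a retinoid-responsive membrane protein, was 4.77-fold higher in small follicles, at 929.9 ± 99.5 FPKM (log2 fold change -2.27, SE 0.25, limma adjusted p = 0.00349). IFI6, an interferon-induced mitochondrial protein, and CXCL9, an interferon-induced chemokine, had log2 fold changes of -2.15 ± 0.36 and -2.26 ± 0.38. ADGRG1, an adhesion receptor, EGFLAM, a matrix protein, AMY2, an amylase, and MAL2, a transcytosis protein, had log2 fold changes of -1.998 ± 0.33, -2.32 ± 0.32, -2.61 ± 0.32 and -2.08 ± 0.38. ND5, a complex I subunit encoded in the mitochondrial genome, had 149 ± 89.7 against 584 ± 94.2 FPKM (log2 fold change -2.12, SE 0.40, limma adjusted p = 0.0476). The fold of small over large was 2.61 against 4.44 for ADGRG1, 4.30 against 6.90 for CXCL9 and 4.02 against 6.08 for MAL2 without small follicle replicate 2, and 5.98 against 3.93 for ND5 without large follicle replicate 2. Of these 20 genes, LCN2, GSTA1, PENK, CYP17A1, SULT2A1, FBXO2, LYZ, HDC, PLA2G1B and RARRES1 stayed called whichever library was left out. The others lost the call in places. Leaving out large follicle replicate 1 gave limma adjusted p values of 0.0665 for MIR9788-1, 0.0563 for CHI3L1, 0.0775 for INHBB, 0.0563 for AMY2, 0.0545 for EGFLAM, 0.0902 for CXCL9, 0.0545 for IFI6, 0.144 for ND5, 0.168 for MAL2 and 0.114 for ADGRG1. Leaving out small follicle replicate 1 gave limma adjusted p values of 0.0789 for CHI3L1, 0.0671 for EGFLAM, 0.122 for IFI6 and 0.156 for ND5. Leaving out small follicle replicate 2 gave limma adjusted p values of 0.0817 for INHBB, 0.172 for CXCL9, 0.102 for ND5, 0.243 for MAL2 and 0.0910 for ADGRG1. With no filter on low values, where 23353 genes entered, 27 of the 128 remained called. There the limma adjusted p was 0.147 for MIR9788-1, 0.140 for CYP17A1, 0.0996 for SULT2A1, 0.0959 for FBXO2, 0.151 for CHI3L1, 0.0764 for HDC, 0.166 for INHBB, 0.0786 for AMY2, 0.0959 for EGFLAM, 0.151 for CXCL9, 0.161 for IFI6, 0.219 for ND5, 0.180 for MAL2 and 0.154 for ADGRG1. With voom it was 0.0779 for MIR9788-1, 0.0897 for CHI3L1, 0.0868 for CXCL9, 0.0868 for ND5 and 0.0607 for MAL2. With median-of-ratios scaling it was 0.102 for IFI6 and 0.131 for ND5.

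**Figure D1:**
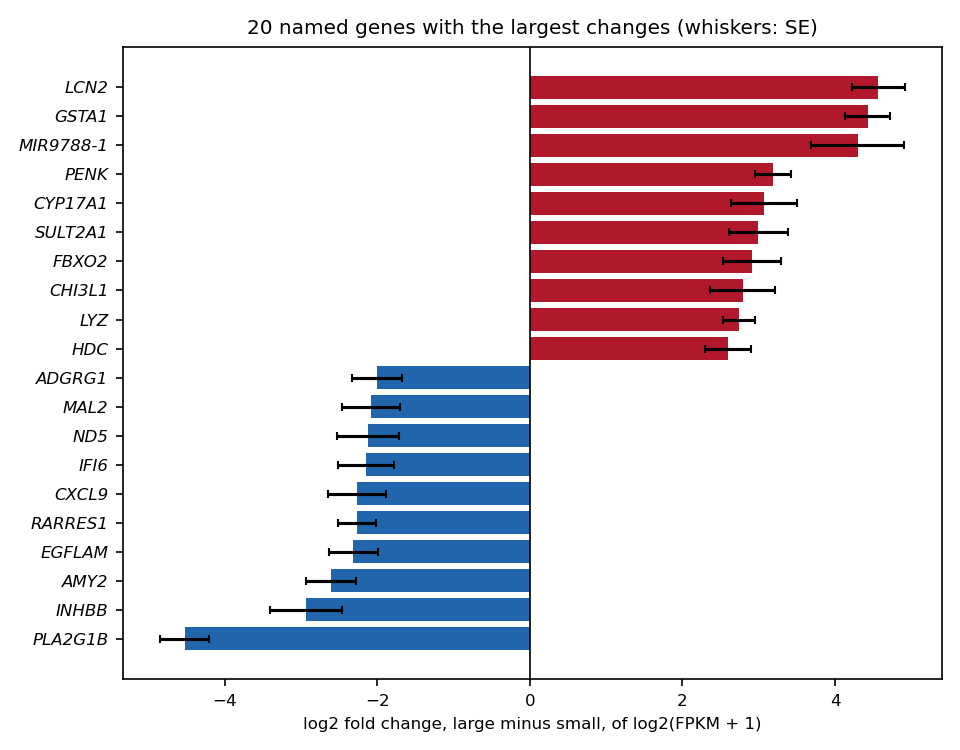
Log2 fold change (large minus small, on the log2(FPKM + 1) scale, x axis) of the 20 named genes with the largest changes, with whiskers of 1 SE; red bars are higher and blue bars lower in large follicles. LCN2 at 4.56 and PLA2G1B at -4.52 lie at the ends.

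Within the steroidogenesis list, 15 of 22 tested members had higher values and 7 lower ones, and the list was called higher (camera adjusted p = 0.00460, and adjusted p = 0.642 with an estimated correlation). Calls were 1 higher and 0 lower over all genes tested, and 6 higher and 3 lower adjusted over the list alone. Beside CYP17A1, the cholesterol transporter STAR had 169 ± 67.4 against 48.6 ± 18.4 FPKM (log2 fold change 1.75, SE 0.35, limma adjusted p = 0.0604). The side-chain cleavage enzyme CYP11A1 had 231 ± 77.6 against 104 ± 33.1 FPKM (log2 fold change 1.13, SE 0.31, limma adjusted p = 0.170). HSD17B1, which reduces estrone to estradiol in granulosa cells, went the other way at a log2 fold change of -1.29 ± 0.30 (limma adjusted p = 0.0956). HSD3B1, which forms progesterone, had a log2 fold change of 0.63 ± 0.31 (limma adjusted p = 0.544). Aromatase fragments sat almost wholly at CYP19A3, at 743 ± 349.7 against 231 ± 119.8 FPKM (limma adjusted p = 0.181). CYP19A1 stayed under the filter with 10, 21 and 11 fragments in large and 2 and 4 in small follicles. The pig aromatase genes are near-identical copies, so which copy these fragments came from is uncertain. The camera adjusted p of the list was 0.114 without large follicle replicate 2, 0.0682 with quantile normalization, 0.0854 with library weights, 0.0725 with the length trend removed and 0.373 without large follicle replicate 2 and small follicle replicate 1. Its median log2 fold change was 0.30, -0.03 without small follicle replicate 1 and 0.61 without small follicle replicate 2. The camera direction stayed higher where the median was -0.03. Limma adjusted p was 0.0139 for STAR and 0.0223 for HSD17B1 without large follicle replicate 2, and 0.00822 for STAR without large follicle replicate 3.

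**Figure D2:**
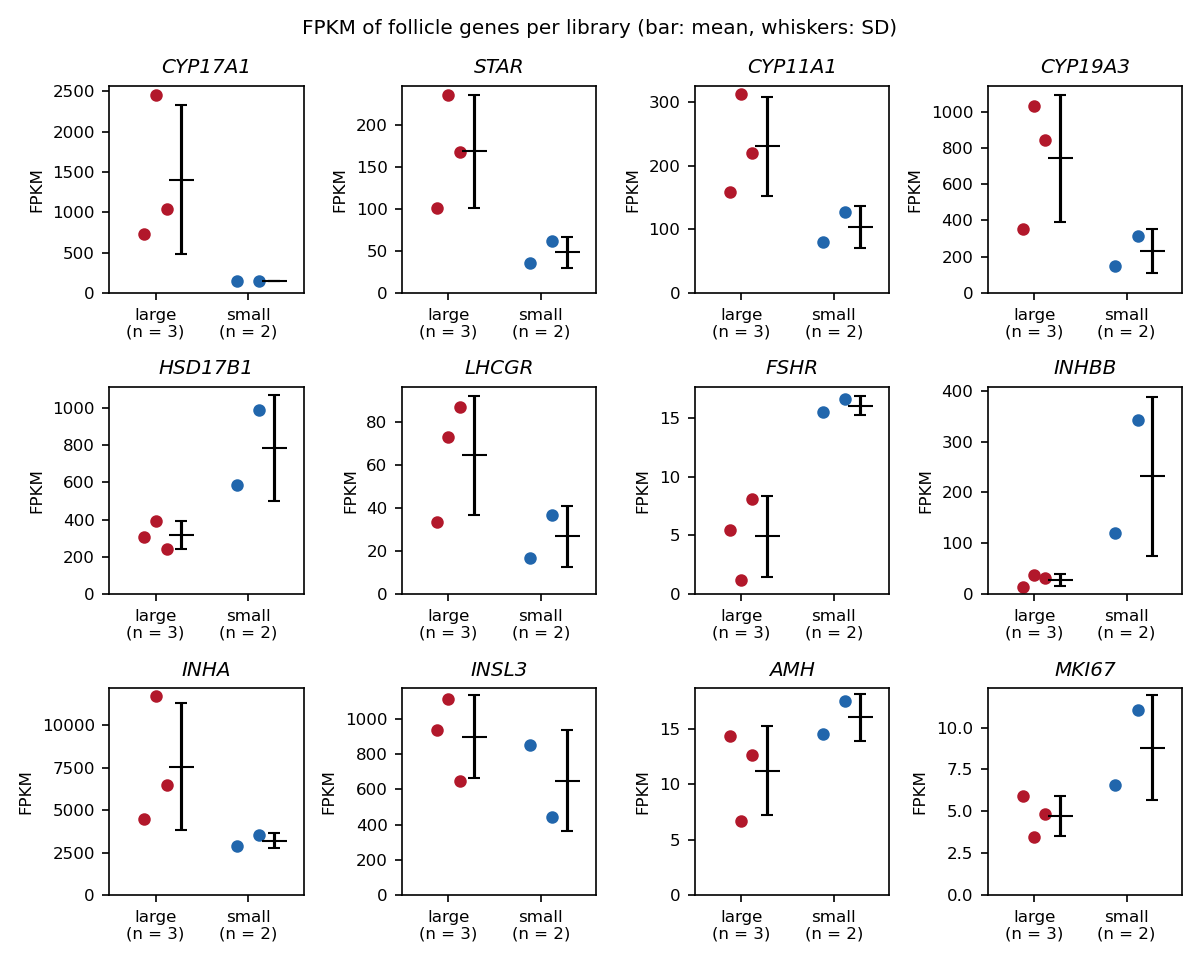
FPKM (y axis, linear from 0) of 12 follicle genes in each library of large (red, n = 3) and small (blue, n = 2) follicles; black bars are group means and whiskers the SD. CYP17A1 lies between 726 and 2451 in the large and at 145 and 147 in the small libraries, whereas INSL3 values of the groups overlap.

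Granulosa and theca markers went both ways. In the granulosa list 7 of 19 tested members had higher values and 12 lower ones (camera adjusted p = 0.291). Calls were 0 higher and 1 lower over all genes tested, and 1 higher and 3 lower adjusted over the list alone. The receptor of follicle-stimulating hormone, FSHR, had 4.91 ± 3.46 against 16.0 ± 0.812 FPKM (limma adjusted p = 0.201). The inhibin alpha subunit INHA had 7555 ± 3756 against 3196 ± 452 FPKM (limma adjusted p = 0.443). TNNI3, a troponin, and FST, which binds activin, had log2 fold changes of 1.23 ± 0.28 and 0.65 ± 0.24 with limma adjusted p values of 0.0875 and 0.359. AMH, a hormone of growing follicles, and INHBA had -0.53 ± 0.32 and 0.16 ± 0.44, with limma adjusted p values of 0.662 and 0.945. The annotated locus of INHBA is of undefined type and shorter than the length that its FPKM and fragments imply, so its level is uncertain. In the theca list 10 of 19 tested members had higher values and 9 lower ones (camera adjusted p = 0.118). Calls were 1 higher and 0 lower over all genes tested, and 3 higher and 1 lower adjusted over the list alone. The luteinizing hormone receptor LHCGR had 64.6 ± 27.7 against 26.8 ± 14.1 FPKM (limma adjusted p = 0.311). INSL3, a theca peptide hormone, had 900.1 ± 237 against 649 ± 287 FPKM (limma adjusted p = 0.713). The hedgehog target GLI1 had a log2 fold change of -1.02 ± 0.31 (limma adjusted p = 0.235). PGR, the progesterone receptor, and VEGFA, an angiogenic factor, had log2 fold changes of -0.02 ± 0.25 and 0.00 ± 0.41, with limma adjusted p values of 0.989 and 0.998. Limma adjusted p was 0.0775 for INHBB without large follicle replicate 1, 0.00696 for FSHR and 0.0404 for TNNI3 without large follicle replicate 3, and 0.0817 for INHBB without small follicle replicate 2. The camera adjusted p of the theca list was 0.0176 without large follicle replicate 3, 0.0198 without small follicle replicate 1, 0.0206 at a mean FPKM of at least 5 and 0.0362 with libraries scaled to a common sum. The theca median was 0.04, and -0.09 under that last scaling, so it differed there in sign from the test.

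Myeloid, lymphocyte, red blood cell and endothelial markers had higher values in large follicles. In the myeloid list 21 of 23 tested members had higher values and 2 lower ones, with a median log2 fold change of 0.52 (camera adjusted p = 4.19e-10, and adjusted p = 0.493 with an estimated correlation). Calls were 1 higher and 0 lower over all genes tested, and 7 higher and 0 lower adjusted over the list alone. After LYZ, the members with the smallest p were the adaptor TYROBP at 1.21 ± 0.28, the neutrophil protein S100A12 at 3.67 ± 0.96 and AIF1 at 1.06 ± 0.28, with limma adjusted p values of 0.0920, 0.144 and 0.146. In the lymphocyte list 14 of 17 tested members had higher values and 3 lower ones (camera adjusted p = 0.0134, and adjusted p = 0.493 with an estimated correlation), with 1 member, CD4, at 1.17 ± 0.26 (limma adjusted p = 0.0813), passing when adjusted over the list alone and 0 over all genes, where 1 passed limma at an unadjusted p under 0.05 and 0 passed voom. In the erythroid list 6 of 9 tested members had higher values and 3 lower ones (camera adjusted p = 0.0305, and adjusted p = 0.493 with an estimated correlation). The hemoglobin chain HBB had 1318 ± 334 against 464 ± 329 FPKM (limma adjusted p = 0.142), a log2 fold change of 1.68 ± 0.44 that was 0.89 without small follicle replicate 2 (limma adjusted p = 0.718). AHSP, which stabilizes hemoglobin alpha chains, had a log2 fold change of 1.31 ± 0.27 (limma adjusted p = 0.0627), and calls in the list were 0 higher and 1 lower over all genes tested, and 4 higher and 1 lower adjusted over the list alone. The camera adjusted p of the erythroid list was 0.106 without large follicle replicate 2, 0.416 without small follicle replicate 2, 0.125 with median-of-ratios scaling, 0.128 with quantile normalization, 0.0671 with voom and 0.111 with the length trend removed. That of the lymphocyte list was 0.106 without large follicle replicate 2, 0.411 without small follicle replicate 2, 0.360 with no filter, 0.0567 with library weights, 0.0551 with a replicate block and 0.202 with the length trend removed. In the endothelial list 21 of 28 tested members had higher values and 7 lower ones (camera adjusted p = 0.000280, and adjusted p = 0.636 with an estimated correlation), and the water channel AQP1 was its called member (log2 fold change 1.10, SE 0.19, limma adjusted p = 0.0316), followed by the adhesion molecule PECAM1 at 0.58 ± 0.20 (limma adjusted p = 0.309). Calls were 1 higher and 0 lower over all genes tested, and 1 higher and 0 lower adjusted over the list alone. AQP1 lost its call in other fits of all libraries. Its limma adjusted p was 0.0937 with no filter, 0.0513 with median-of-ratios scaling and 0.0895 with libraries scaled to a common sum. It was 0.109 with a replicate block and 0.0586 with voom. Limma adjusted p was 0.0995 for AQP1 without large follicle replicate 1, 0.0431 for AHSP and 0.0217 for S100A12 without large follicle replicate 2, 0.0316 for AHSP, 0.0215 for TYROBP, 0.0192 for HBB and 1.41e-06 for S100A12 without large follicle replicate 3, 0.198 for AQP1 and 0.0158 for HBB without small follicle replicate 1, and 0.143 for AQP1 without small follicle replicate 2. Mitochondrial mRNA, which can shift with RNA quality, took 4.31% of fragments in large and 6.38% in small follicles.

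Immune response genes split. In the interferon list 4 of 25 tested members had higher values and 21 lower ones (camera adjusted p = 0.0134, and adjusted p = 0.642 with an estimated correlation). Calls were 1 higher and 2 lower over all genes tested, and 2 higher and 4 lower adjusted over the list alone. ISG15, a ubiquitin-like protein, fell with IFI6 (log2 fold change -1.34, SE 0.22, limma adjusted p = 0.0293). OAS1, an antiviral synthetase, rose (log2 fold change 1.496, SE 0.26, limma adjusted p = 0.0337). MX1, an antiviral GTPase, had a log2 fold change of -0.88 ± 0.21 (limma adjusted p = 0.0982). The interferon list had a camera adjusted p of 0.1103 without small follicle replicate 1, 0.108 without that library and large follicle replicate 2 and 0.106 at a mean FPKM of at least 5. The inflammation list was not called (camera adjusted p = 0.322), with calls of 2 higher and 1 lower over all genes tested, and 4 higher and 3 lower adjusted over the list alone; its median was -0.05 and its mean 0.16. CXCL14, a chemokine, rose (log2 fold change 2.36, SE 0.40, limma adjusted p = 0.0310). LCN2, described above, was the other gene of this list called higher. SAA3, an acute-phase protein, had a log2 fold change of 1.40 ± 0.28 (limma adjusted p = 0.0598). SAA3 had a limma adjusted p of 0.0302 without large follicle replicate 2 and 0.0251 without large follicle replicate 3. As given above, LCN2 stayed called whichever library was left out. Each other call among these genes was lost in places. Without large follicle replicate 1 limma adjusted p was 0.0563 for ISG15, 0.0545 for IFI6, 0.169 for OAS1, 0.0902 for CXCL9 and 0.0760 for CXCL14. With voom it was 0.0868 for ISG15, 0.0872 for OAS1, 0.0868 for CXCL9 and 0.0773 for CXCL14. Without small follicle replicate 1 log2 fold changes were -1.36 for ISG15, -1.71 for IFI6, 1.46 for OAS1, -2.79 for CXCL9 and 2.11 for CXCL14. Without small follicle replicate 2 they were -1.31, -2.58, 1.53, -1.73 and 2.61 in the same order.

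Cell-cycle and early-response genes were lower as lists. In the cell-cycle list 1 of 47 tested members had higher values and 46 lower ones, with a median of -0.57 (camera adjusted p = 1.59e-08, and adjusted p = 0.642 with an estimated correlation). No single member was called by limma over all genes or adjusted over the list alone, 11 were lower at an unadjusted p under 0.05, and voom called 0. The values of 17 members did not overlap between the groups. The list mean of small follicle replicate 1, as log2 deviation from the mean of all libraries, was 0.02, at the level of large follicle replicate 1 (0.03), with -0.52 and -0.16 in large follicle replicates 2 and 3 and 0.62 in small follicle replicate 2. The median was -0.23 without small follicle replicate 2 (camera adjusted p = 9.32e-05), -0.38 without large follicle replicate 2 and -0.94 without small follicle replicate 1. The replication helicase subunits MCM2 and MCM5 had -1.04 ± 0.25 and -0.87 ± 0.23 (limma adjusted p = 0.0991 and 0.144), and the proliferation marker MKI67 -0.76 ± 0.32 (limma adjusted p = 0.450). In the early-response list 5 of 30 tested members had higher values and 25 lower ones (camera adjusted p = 0.00393, and adjusted p = 0.704 with an estimated correlation), with 0 called over all genes, 8 lower at an unadjusted p under 0.05, 0 called by voom and 3 lower adjusted over the list alone. Its list means, as log2 deviations from the mean of all libraries, were 0.05, -0.60 and 0.06 in large follicle replicates 1, 2 and 3. They were -0.11 and 0.61 in small follicle replicates 1 and 2. Small follicle replicate 1 thus lay below large follicle replicates 1 and 3. FOSB, FOS and EGR1, transcription factors induced within minutes of a stimulus, had log2 fold changes of -1.57 ± 0.31, -1.63 ± 0.38 and -1.65 ± 0.45, with limma adjusted p values of 0.0587, 0.0973 and 0.160. Limma adjusted p was 0.0437 for FOSB, 0.0456 for FOS and 0.0449 for EGR1 without large follicle replicate 2, 0.0301 for FOSB, 0.00230 for FOS and 0.00364 for EGR1 without large follicle replicate 3, and 0.0262 for FOS without small follicle replicate 1. The early-response list had a camera adjusted p of 0.0515 without large follicle replicate 2 and 0.242 without small follicle replicate 2.

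Nuclear genes of protein synthesis and respiration were higher as lists and mitochondrial mRNA lower. All 72 ribosomal protein genes had higher mean values in large follicles, with a median of 0.41 (camera adjusted p = 1.40e-10, and adjusted p = 0.677 with an estimated correlation). None was called by limma over all genes, 1 was higher at an unadjusted p under 0.05, voom called 0, and 23 did not overlap between the groups; none passed adjusted over the list alone. The members with the smallest p were RPL9 at 0.63 ± 0.27 (limma adjusted p = 0.455) and RPL23 at 0.79 ± 0.35 (limma adjusted p = 0.480). Their direction held under each scaling by list median, but the median was 0.08 with quantile normalization (camera adjusted p = 0.151), and without small follicle replicate 2 the median was 0.11 and the camera adjusted p 0.948. Without small follicle replicate 1 the median was 0.71. List means, as log2 deviations from the mean of all libraries, were 0.41, 0.15 and -0.07 in large follicle replicates 1, 2 and 3. They were 0.06 and -0.54 in small follicle replicates 1 and 2. In the nuclear oxidative phosphorylation list 41 of 43 tested members had higher values and 2 lower ones (camera adjusted p = 5.98e-08, and adjusted p = 0.493 with an estimated correlation), with NDUFB2 at 0.62 ± 0.21 and NDUFA2 at 0.66 ± 0.23, both subunits of complex I (limma adjusted p = 0.310 and 0.318). None of these was called by limma over all genes or adjusted over the list alone, 5 were higher at an unadjusted p under 0.05, and voom called 0. All 13 mRNAs of the mitochondrial genome had lower values, with a median of -0.96 (camera adjusted p = 1.09e-05, and adjusted p = 0.642 with an estimated correlation). Calls were 0 higher and 1 lower over all genes tested, and 0 higher and 5 lower adjusted over the list alone. Beside ND5, the complex I subunit ND6 had a log2 fold change of -1.46 ± 0.31 (limma adjusted p = 0.0743). Mitochondrial mRNA took 4.31% ± 1.79 of fragments (SD, n = 3) in large and 6.38% ± 3.05 (SD, n = 2) in small follicles. The groups overlapped in this share, since large follicle replicate 2 had 6.36% (Wilson 95% interval 6.35 to 6.38) and small follicle replicate 2 4.22% (4.21 to 4.23). Without small follicle replicate 1 the camera adjusted p of the mitochondrial list was 0.1103, and the limma adjusted p of ND5 was 0.144 without large follicle replicate 1, 0.156 without small follicle replicate 1 and 0.102 without small follicle replicate 2. ND6 had a limma adjusted p of 0.0139 without large follicle replicate 2. The median was -0.55 without small follicle replicate 1.

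Oocyte, protease and antioxidant lists were called higher. In the oocyte list 11 of 16 tested members had higher values and 5 lower ones (camera adjusted p = 0.00886, and adjusted p = 0.493 with an estimated correlation), and ZP4, a zona pellucida protein, had 13.8 ± 0.961 against 4.84 ± 1.71 FPKM (limma adjusted p = 0.0580), beside KHDC3L, of the subcortical maternal complex, at 1.06 ± 0.34 (limma adjusted p = 0.263). No oocyte gene was called over all genes; 3 were higher at an unadjusted p under 0.05, voom called 0, and 1 passed adjusted over the list alone. The camera adjusted p was 0.0607 without large follicle replicate 2, 0.516 without small follicle replicate 2 and 0.129 with the length trend removed, and the limma adjusted p of ZP4 was 0.0473 without large follicle replicate 2. In the protease and inhibitor list 21 of 33 tested members had higher values and 12 lower ones (camera adjusted p = 0.000468, and adjusted p = 0.642 with an estimated correlation), and the called member SERPINF1, an antiangiogenic serpin, had 35.8 ± 4.01 against 6.17 ± 0.279 FPKM (log2 fold change 2.35, SE 0.22, limma adjusted p = 0.00131), followed by the matrix metalloproteinase MMP19 at 0.95 ± 0.26 (limma adjusted p = 0.167). Calls were 1 higher and 0 lower over all genes tested, and 1 higher and 0 lower adjusted over the list alone. That list had a camera adjusted p of 0.0913 without large follicle replicate 2 and small follicle replicate 1. Its median was 0.20, -0.02 without small follicle replicate 1 and 0.42 without small follicle replicate 2. In the antioxidant list 15 of 29 tested members had higher values and 14 lower ones (camera adjusted p = 0.0133, and adjusted p = 0.493 with an estimated correlation). Its median was 0.00, its mean 0.27, and the median was -0.12 when libraries were scaled to a common sum, -0.02 with quantile normalization, -0.03 with the length trend removed, and -0.02 and -0.01 without large and without small follicle replicate 1. Beside GSTA1, the glutathione peroxidase GPX1 rose (log2 fold change 1.20, SE 0.23, limma adjusted p = 0.0476). Calls were 2 higher and 0 lower over all genes tested, and 5 higher and 0 lower adjusted over the list alone. The limma adjusted p of GPX1 was 0.149 without large follicle replicate 1, 0.128 without small follicle replicate 1 and 0.306 without small follicle replicate 2, 0.151 with median-of-ratios scaling and 0.0685 with voom. The camera adjusted p of the antioxidant list was 0.114 without large follicle replicate 2, 0.246 without small follicle replicate 2, 0.256 with quantile normalization and 0.403 with the length trend removed.

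**Figure D3:**
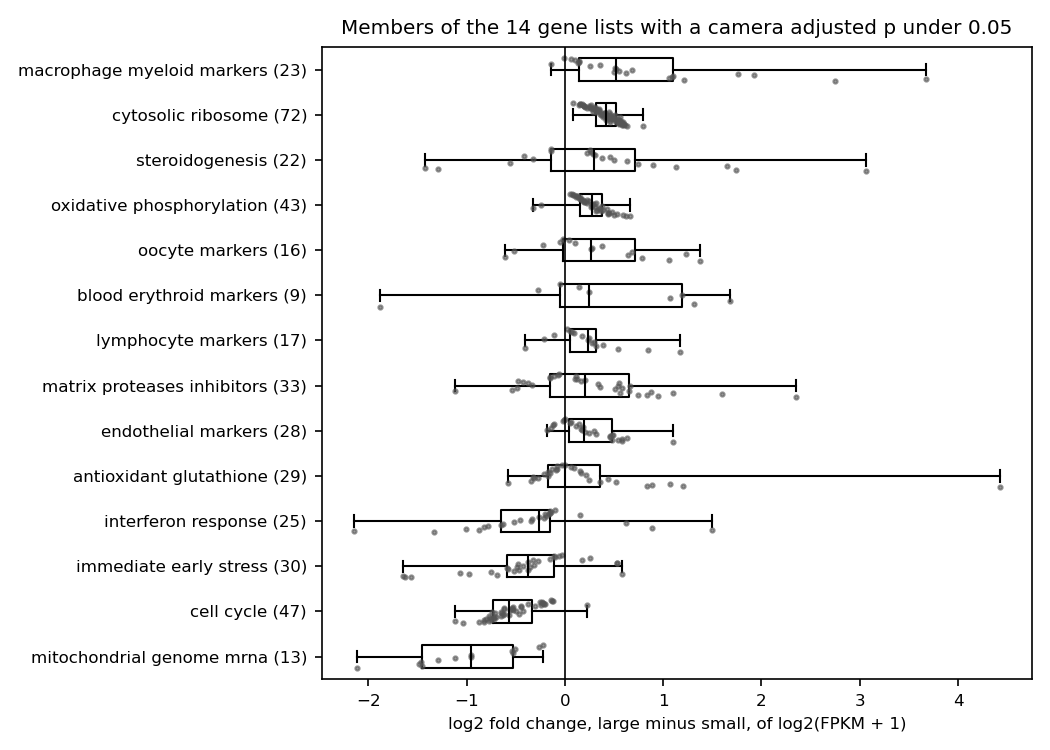
Log2 fold change (large minus small, x axis) of each tested member (grey points) of the 14 gene lists called by camera at the preset correlation, with the number tested in brackets; boxes span the quartiles, black lines are medians and whiskers reach the extremes. Medians run from -0.96 for mitochondrial mRNA to 0.52 for myeloid markers, and no list was called with an estimated correlation.

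The other lists were not called by camera. In the Notch and hedgehog list (camera adjusted p = 0.0522), 6 members had higher and 19 lower values. Of the Notch and hedgehog genes limma called 0 over all genes (4 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 1 lower adjusted over the list alone. IHH, a hedgehog ligand of granulosa cells, had a log2 fold change of -2.91 ± 0.60 (limma adjusted p = 0.0648), beside GLI1 at -1.02 ± 0.31 (limma adjusted p = 0.235). The camera adjusted p was 0.0330 without large follicle replicate 1, 0.0214 without large follicle replicate 3 and 0.0327 with voom. Limma adjusted p of IHH was 0.000445 without large follicle replicate 2 and 0.000560 without large follicle replicate 3. In the Wnt list (camera adjusted p = 0.157), 11 members had higher and 26 lower values. Of the Wnt genes limma called 1 over all genes and 1 higher and 0 lower adjusted over the list alone. The Wnt antagonist SFRP4 rose with a log2 fold change of 1.76 ± 0.27 (limma adjusted p = 0.0194), beside TCF7 at -0.88 ± 0.27 (limma adjusted p = 0.242). The limma adjusted p of SFRP4 was 0.0997 without large follicle replicate 1, 0.0790 without small follicle replicate 1 and 0.129 without small follicle replicate 2. In the TGF-beta family list (camera adjusted p = 0.236), 14 members had higher and 23 lower values. Of the TGF-beta family genes limma called 1 over all genes and 0 higher and 1 lower adjusted over the list alone. INHBB fell with a log2 fold change of -2.94 ± 0.47 (limma adjusted p = 0.0237), beside SMAD3 at -0.84 ± 0.32 (limma adjusted p = 0.367). The limma adjusted p of INHBB was 0.0775 without large follicle replicate 1 and 0.0817 without small follicle replicate 2. In the IGF system list (camera adjusted p = 0.322), 4 members had higher and 11 lower values. Of the IGF system genes limma called 0 over all genes (0 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 0 lower adjusted over the list alone. STC1 had a log2 fold change of -0.83 ± 0.39 (limma adjusted p = 0.512), beside IGF1 at 0.47 ± 0.23 (limma adjusted p = 0.543). In the hormone receptor list (camera adjusted p = 0.590), 7 members had higher and 11 lower values. Of the hormone receptor genes limma called 0 over all genes (4 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 0 lower adjusted over the list alone. KIT, the receptor of KIT ligand, had a log2 fold change of -1.39 ± 0.36 (limma adjusted p = 0.135), beside AMHR2 at 0.92 ± 0.29 (limma adjusted p = 0.2504). For KIT and FSHR the limma adjusted p was 0.00696 for FSHR without large follicle replicate 3, and 0.0431 for KIT without small follicle replicate 1. In the ovulation list (camera adjusted p = 0.505), 7 members had higher and 13 lower values. Of the ovulation genes limma called 0 over all genes (3 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 0 lower adjusted over the list alone. The prostaglandin E synthase PTGES had a log2 fold change of 1.298 ± 0.40 (limma adjusted p = 0.246), beside AREG at -0.93 ± 0.35 (limma adjusted p = 0.370). In the cholesterol synthesis list (camera adjusted p = 0.236), 11 members had higher and 11 lower values. Of the cholesterol synthesis genes limma called 0 over all genes (4 at an unadjusted p under 0.05 and 0 by voom) and 1 higher and 1 lower adjusted over the list alone. The sterol reductase TM7SF2 had a log2 fold change of 1.34 ± 0.32 (limma adjusted p = 0.102), beside FDPS at 0.75 ± 0.22 (limma adjusted p = 0.209). For TM7SF2 the limma adjusted p was 0.0381 without large follicle replicate 3. Without large follicle replicate 1 the camera adjusted p of the list was 0.00546. In the apoptosis list (camera adjusted p = 0.954), 12 members had higher and 18 lower values. Of the apoptosis genes limma called 0 over all genes (2 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 0 lower adjusted over the list alone. The secreted chaperone CLU had a log2 fold change of 1.01 ± 0.26 (limma adjusted p = 0.144), beside the pro-apoptotic BAD at 0.40 ± 0.22 (limma adjusted p = 0.597).

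Tissue and stroma lists were not called either. In the extracellular matrix list (camera adjusted p = 0.157), 25 members had higher and 17 lower values. Of the extracellular matrix genes limma called 0 over all genes (7 at an unadjusted p under 0.05 and 0 by voom) and 2 higher and 1 lower adjusted over the list alone. Elastin, ELN, had a log2 fold change of 1.28 ± 0.25 (limma adjusted p = 0.0562), beside the fibulin FBLN1 at 0.97 ± 0.23 (limma adjusted p = 0.0956) and the basement membrane proteoglycan HSPG2 at -1.16 ± 0.30 (limma adjusted p = 0.137). Without large follicle replicate 1 the camera adjusted p of the list was 0.00755, and with the length trend removed it was 0.0204. Limma adjusted p was 0.0275 for ELN and 0.0279 for HSPG2 without large follicle replicate 2, and 0.0159 for ELN and 0.0248 for HSPG2 without large follicle replicate 3. In the stroma list (camera adjusted p = 0.157), 13 members had higher and 8 lower values. Of the stroma genes limma called 1 over all genes and 1 higher and 0 lower adjusted over the list alone. MFAP4, a microfibril protein, rose with a log2 fold change of 1.75 ± 0.21 (limma adjusted p = 0.00641), beside the proteoglycan LUM at -0.73 ± 0.41 (limma adjusted p = 0.630). Without small follicle replicate 1 the camera adjusted p of the list was 0.0435. In the smooth muscle list (camera adjusted p = 0.560), 7 members had higher and 11 lower values. Of the smooth muscle genes limma called 0 over all genes (4 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 1 lower adjusted over the list alone. The actin-binding LMOD1 had a log2 fold change of -1.01 ± 0.23 (limma adjusted p = 0.0904), beside the smooth muscle myosin MYH11 at -0.77 ± 0.26 (limma adjusted p = 0.309). The limma adjusted p of LMOD1 was 0.0360 without large follicle replicate 3. In the angiogenesis and hypoxia list (camera adjusted p = 0.505), 10 members had higher and 17 lower values. Of the angiogenesis and hypoxia genes limma called 0 over all genes (3 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 1 lower adjusted over the list alone. The hypoxia-inducible factor EPAS1 had a log2 fold change of -1.60 ± 0.37 (limma adjusted p = 0.0915), beside HIF1A at -1.21 ± 0.51 (limma adjusted p = 0.450). The limma adjusted p of EPAS1 was 0.00885 without large follicle replicate 2 and 0.00379 without large follicle replicate 3. In the surface epithelium list (camera adjusted p = 0.202), 3 members had higher and 2 lower values. Of the surface epithelium genes limma called 0 over all genes (3 at an unadjusted p under 0.05 and 0 by voom) and 1 higher and 0 lower adjusted over the list alone. The keratin KRT19 had a log2 fold change of 1.36 ± 0.37 (limma adjusted p = 0.153), beside KRT7 at 0.78 ± 0.33 (limma adjusted p = 0.450). In the complement and coagulation list (camera adjusted p = 0.0920), 19 members had higher and 8 lower values. Of the complement and coagulation genes limma called 0 over all genes (6 at an unadjusted p under 0.05 and 0 by voom) and 0 higher and 0 lower adjusted over the list alone. The terminal complement component C9 had a log2 fold change of 0.87 ± 0.25 (limma adjusted p = 0.199), beside the protease inhibitor A2M at -0.83 ± 0.25 (limma adjusted p = 0.214). Without large follicle replicate 1 the camera adjusted p of the list was 0.0314. With fry, which asks whether the members of a list move on balance 1 way, 0 of the 31 lists passed (lowest adjusted p = 0.170). At an unadjusted p under 0.05 fry passed 3, and 14 passed its test for change in either direction. Camera with an estimated correlation called 0, and 2 had an unadjusted p under 0.05.

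The distance between libraries did not follow follicle size alone. Pearson correlations across the genes tested, which are not independent replicates, ran from 0.969 to 0.978 between large follicle libraries, reached 0.976 between the small ones, and ran from 0.943 to 0.965 between groups. The first component held 47.6% and the second 32.5% of the variance. On the first component large follicle replicate 3, at 8.72, lay between small follicle replicates 1 and 2, at 0.548 and 45.9. Large follicle replicates 1 and 2 lay at -13.2 and -41.9 there. On the second component large follicle replicate 2 lay with the small follicle libraries, away from large follicle replicates 1 and 3. Setting large follicle replicate 2 and small follicle replicate 1, the libraries of highest mitochondrial share in their groups, against the other 3 libraries gave 2670 genes at an unadjusted limma p under 0.05, more than the 1365 for follicle size, and 0 after adjustment. Without this pair, an alternative chosen after the data were examined, 390 genes were called, with 120 of the 128 among them, and the lone small library was assumed to vary like the large ones.

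**Figure D4:**
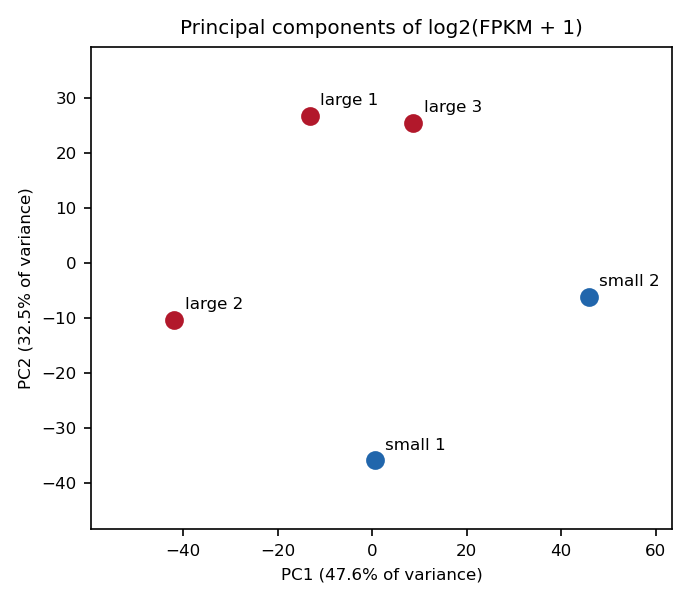
Principal components 1 (x axis) and 2 (y axis) of log2(FPKM + 1) over the 13087 genes tested, 1 point per library, large follicles red and small follicles blue. Large follicle replicates 1 and 3 lie at 26.8 and 25.6 on the second component, replicate 2 at -10.3, between the small follicle libraries at -6.13 and -35.9.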

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

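The removal of a gene length trend, voom with median-of-ratios scaling and leaving out 2 libraries were chosen after the data were examined. The 128 genes called (70 higher, 58 lower) became 32 (15 higher, 17 lower) with no filter, 41 (31 higher, 10 lower) at a mean FPKM of at least 5, 202 (122 higher, 80 lower) with median-of-ratios scaling, 201 (118 higher, 83 lower) with quantile normalization, 82 (41 higher, 41 lower) among protein-coding genes, 70 (39 higher, 31 lower) with voom, 186 (91 higher, 95 lower) with voom and that scaling, 191 (102 higher, 89 lower) with the length trend removed, and 390 (157 higher, 233 lower) without large follicle replicate 2 and small follicle replicate 1. The cause of these moves was not tested, beyond the number of genes or libraries entering each fit. Leaving out 1 library gave 29 to 268 called genes, 23 to 163 higher and 6 to 105 lower, lowest without large follicle replicate 1 and highest without replicate 2, and 8 to 18 lists against 14. Where 1 small library was left, its spread was assumed to be that of the large group. All 128 kept their direction in each fit that tested them. With the inter-gene correlation estimated 0 lists were called by camera, with a lowest adjusted p of 0.493, against 14 at the preset value. With a replicate block 157 genes and 17 lists were called. Whether the replicate numbers pair the samples is not given in the sources used here. Deviations of same-numbered libraries from their group means correlated at -0.00148 and -0.449 across genes. The deviations of the 2 small libraries mirror each other by construction, so these correlations cannot tell whether samples were paired. The mean correlation within groups exceeded that between groups by 0.0175, by 0.0297 with a pseudocount of 0.1 and by 0.00809 with no filter. The median of all genes was -0.08, 0.00 with median-of-ratios scaling and -0.20 with libraries scaled to a common sum. Over all alternatives, named genes kept direction and side of the threshold in 2559 fits, lost the call in 116, gained it in 114 and, uncalled, changed sign in 20; for lists these were 596, 48, 21 and 13. No called list changed its camera direction, but the medians of the antioxidant, steroidogenesis and protease lists turned negative in some fits.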

Other observations

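The tests below on library value distributions, single libraries, cell shares, blood and other groupings, and the genes of the next 2 paragraphs, were chosen after their values were seen; the length test was written before its result.

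Genes annotated as C regions or V segments, which are parts of antigen receptors, made up 8 of the 128 called genes, 7 of them higher in large follicles. Which of these are immunoglobulin and which T-cell receptor segments was not checked. MZB1, a chaperone of antibody secretion, had 8.71 ± 2.41 against 1.88 ± 0.498 FPKM (limma adjusted p = 0.0398). The class II gene SLA-DRB1 had 69.7 ± 6.79 against 22.3 ± 1.08 FPKM (limma adjusted p = 0.00647) and SLA-DQB1 a log2 fold change of 1.10 ± 0.19, while the class I gene SLA-3 had 36.0 ± 6.42 against 89.0 ± 8.69 FPKM (limma adjusted p = 0.0316). Antigen receptor segments and histocompatibility genes are families of similar and variable sequences, so their levels are uncertain. Limma adjusted p was 0.172 for MZB1, 0.108 for SLA-DQB1 and 0.0867 for SLA-3 without large follicle replicate 1, 0.0879 for MZB1, 0.178 for SLA-DQB1 and 0.102 for SLA-3 without small follicle replicate 1, and 0.215 for MZB1, 0.179 for SLA-DQB1 and 0.210 for SLA-3 without small follicle replicate 2.

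Several called genes fall outside the gene lists. HSD11B1, which regenerates active glucocorticoid, had 62.0 ± 5.64 against 20.2 ± 4.77 FPKM (limma adjusted p = 0.0107), and SMOC2, a matricellular protein, 6.60 ± 0.321 against 0.607 ± 0.1004 FPKM (limma adjusted p = 0.00595). MC3R, a melanocortin receptor, had 0.634 ± 0.562 against 9.42 ± 2.06 FPKM (limma adjusted p = 0.00856), CHGA, a protein of secretory granules, 119.8 ± 30.3 against 324 ± 4.75 FPKM (limma adjusted p = 0.0288), and COL22A1, a collagen, 0.0201 ± 0.00906 against 2.50 ± 0.507 FPKM (limma adjusted p = 0.00872). Large follicle replicates 1, 2 and 3 held 1, 1 and 2 fragments of COL22A1, so its level there was near the counting floor. They held 1, 13 and 7 fragments of MC3R. The fold of small over large of MC3R was 14.8, and 26.9 without large follicle replicate 2. RLN2, the hormone relaxin, was not called (limma adjusted p = 0.975) and was listed at 51.4 FPKM in small follicle replicate 2 and at 0 in small follicle replicate 1, with 8.18, 9.99 and 5.18 in the large follicle libraries. Its log2 fold change was -2.62 without small follicle replicate 1 and 3.10 without small follicle replicate 2, with limma adjusted p values of 0.0136 and 0.0115. For the called genes above, limma adjusted p was 0.0665 for HSD11B1, 0.0545 for SMOC2, 0.0563 for MC3R and 0.0708 for COL22A1 without large follicle replicate 1, 0.0845 for HSD11B1 and 0.116 for CHGA without small follicle replicate 1, and 0.120 for CHGA without small follicle replicate 2.

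The real grouping called 128 genes, and the highest of the other groupings into 3 and 2 called 0, so 1 of the 10 groupings reached that count. These groupings are too few for a share under 0.05. At an unadjusted limma p under 0.05, 2 other groupings gave more genes than the 1365 of the real one, 2670 and 2222, which points to structure among the libraries other than follicle size.

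CYP17A1 was higher by 3.07 on the log2 scale while granulosa genes went both ways. If levels within theca cells stayed the same, a larger share of these cells would raise theca markers about as much as CYP17A1. The 14 markers outside the steroidogenesis list had a median of -0.16 and an SD of 0.61. They include hedgehog targets such as GLI1, and the granulosa hedgehog ligand IHH also had lower values. Their median can thus move without a change of theca share and does not decide whether that share differed. For these 14 markers, a median of -0.16 with an SD of 0.61 lies far below 3.07. These values argue against a larger share at unchanged levels as the only source of the CYP17A1 rise. A smaller share of granulosa cells stays open: 3 of the 19 granulosa list members were higher by more than 2 standard errors and 7 were lower, but this count only restates the pattern, and none of the 3 was called over all genes. A change of expression with follicle size was not tested apart from cell shares.

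Ribosomal protein genes were higher and cell-cycle genes lower together, with 0.98 between the list medians. Log2 fold changes fell with gene length across genes (Spearman rho -0.34), and with the length trend removed from each library the distance was 0.72, so length may account for part of it. The distance was 0.58 with quantile normalization. Leaving out small follicle replicate 2 took it to 0.34, and leaving out small follicle replicate 1 took it to 1.65. No value decides between a property of either library, a length bias and a difference between follicle sizes. These lists lost their calls when the correlation between genes was estimated.

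Myeloid genes were higher in large follicles, and more blood in these samples is a candidate source. HBB was higher by 1.68 (SE 0.44), at 1318 ± 334 against 464 ± 329 FPKM, but by 0.89 without small follicle replicate 2 (limma adjusted p = 0.718). HBB was not called with all libraries, the medians of the myeloid and lymphocyte lists differed by 0.29, and 3 of 9 erythroid list members had lower values. The HBB value goes with that explanation but had been seen before it was put, so it is no independent evidence for it. Myeloid cells resident in the follicle wall were not tested apart from blood.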
